A study of Caenorhabditis elegans with 2 samples.

How the data were processed

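The data were transcription factor ChIP-seq peak lists from whole young adult worms of a strain with EGFP and epitope tags at attf-3, with an antibody against GFP. Samples were grouped by their labels into 1 group with 2 biological replicates, whose numbers come from the labels. Per the labels, chromatin was sonicated and the assembly was ce11. Per the deposited file descriptions, each list was derived from alignments of the replicate or replicates and of a control alignment. The aligner, the peak caller and their versions are not given in the sources used here.

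The authors deposited 8 peak lists, 4 for the series and 2 for each replicate: lists ranked by the irreproducible discovery rate (IDR), a measure of how consistently 2 peak rankings order a peak, and lists kept at a threshold on it. Each peak in the deposited lists has a signal value from the authors' caller, whose scale is not stated, a scaled IDR score capped at 1000 and the offset of its summit. The ranked lists give the −log10 of the global IDR, per the authors' column order. Signal values are the authors' own, and were used to describe, rank and divide peaks within a list, to correlate the replicates' values across joint peaks, and to correlate signal with GC percent across the peaks of a list. The deposited p-value column holds no values. The thresholded lists all end at an IDR of 0.01, judged from the deposited scores. Since the lists hold no counts, depth is unknown, and intervals below cover counting error over peaks or genes only. In the ranked lists of the series, 4 columns of signal per replicate carry no name and were not used; values per replicate came from each replicate's own lists.

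The main list was the conservative thresholded list of 1737 peaks, called here the joint list, since it rests on the comparison of the true replicates. Genes came from Ensembl release 115 for WBcel235, which is the same assembly as ce11; sequences came from the RefSeq copy of that assembly. All peaks lay within chromosome lengths. A protein-coding gene was called bound when a summit lay within 500 bp of its annotated 5' end. Non-coding genes were widened by 200 bp. The design, the 36 gene lists (regular expressions on gene symbols) and the alternatives were fixed before the data were examined. The lists were cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, respiratory chain, proteasome, splicing, RNA polymerase, nucleolar, nuclear pore, replication, cell cycle, histone, chromatin, P granule, Argonaute, meiosis, eggshell, sperm, spermatogenesis, vitellogenin, intestine, muscle, collagen, neuronal, neuropeptide, homeobox, nuclear hormone receptor, chemoreceptor, F-box, detoxification, immunity, chaperone, vacuolar ATPase, ubiquitin and attf genes.

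Gene lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Promoter share, chromosome densities and non-coding classes were compared with 10000 random placements of the summits, within chromosomes except for the density on X. AT content and 6-mers used windows of the summit and 50 bp on either side, with control windows at the same signed distance from the 5' ends of random unbound genes, 5 per peak for the 6-mers; fold differences of 6-mers used a pseudocount of 0.5 windows. Shares carry 95% Wilson intervals, and a share of 0 carries the limit of 3 counts of the total. The genes named were those nearest the 25 highest peaks, the attf genes, up to 4 members with the highest signals of each list past the threshold or with at least 5 bound members, the 5 highest peaks over 2000 bp from a 5' end, and up to 3 members of each non-coding class past the threshold; some lists are described with fewer, and 1 member of the chemoreceptor list is not reported here.

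Alternatives fixed beforehand were the list from pooled reads, the stronger 868 peaks, each replicate's own list in turn, windows of 250 and 1000 bp, assignment to the nearest gene only, rotation along the gene order, autosomes only, circular shifts, placement by gene number or at 5' ends, non-coding genes widened by 50 bp, windows of 201 bp, control windows at 1000 bp from the summit, the ranked lists for the attf-3 locus, and other overlap rules. A planned stricter IDR of 0.01 moved nothing, because the lists already end there, and the stronger 868 peaks took its place as planned. Added after seeing the data were an IDR of at most 0.001, the 5' ends of any transcript, placements like the summits at other promoters, and joining of overlapping peaks.

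The statistics were tested on simulated data. In 20 simulated peak sets with 30% of the members of 5 lists bound, 100% of these lists were recovered, with 0.35 other lists called per set and 0 when nothing was planted. The planted lists had at least 20 members, and bound genes were drawn independently. Peaks shared by neighbouring genes, smaller lists and lower shares were therefore not covered. Of 20 6-mers planted in 2.5% of windows each, 85% were recovered, and 0 were called between control windows. Of 20 control sets, 1 differed in AT content at p below 0.05. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Signal tracks were not used here.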

Results

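The series measured where the protein encoded by attf-3, a gene named for an AT-hook DNA-binding domain, lay on the genome of the nematode Caenorhabditis elegans. Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers DNA fragments bound by a protein, and their pile-ups are called as peaks. The worms carried an EGFP and epitope tag inserted at the attf-3 gene by CRISPR, and an antibody against GFP pulled the fusion protein down from whole young adults aged 63 hours. All samples formed 1 group with 2 biological replicates from separate biosamples, so the labels imply no contrast between conditions and no test between groups was made. The files held peak positions and signal values without read counts, and the sequencing depth of each replicate is therefore unknown. Coordinates are on assembly ce11, counted from 1.

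The question for the replicates was how far they placed the protein at the same sites. The peak at the promoter of cmtr-1, which encodes a cap methyltransferase, had the highest signal in the joint list of both replicates, at 5279.66, as well as in replicate 1, at 2670.79, and in replicate 2, at 2611.41. All 25 of the highest peaks of the joint list overlapped a peak in both replicates' own lists. The joint list held 1737 peaks, the list of replicate 1 held 964 and that of replicate 2 held 1063. Of the replicate 1 peaks, 751 of 964 (77.9%, 95% Wilson interval 75.2 to 80.4%) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 747 of 1063 (70.3%, 67.5 to 72.9%) overlapped a replicate 1 peak.

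Of the 1737 joint peaks, 759 (43.7%, 41.4 to 46.04%) were in both replicates' own lists, 410 were in the list of 1 replicate only, and 568 (32.7%, 30.5 to 34.9%) were in neither. With the list split by signal into 10 parts, 100% of the 174 strongest peaks were in both lists, and in part 8 the share was 0 of 174. The longer list exceeded the shorter by 1.10-fold for the replicates, and by 1.02-fold for the joint list against the 1700 peaks of the list from pooled reads. Signal values were then taken from the replicates' ranked lists before the threshold, where 1713 joint peaks had a match in both. They gave Spearman's rho of 0.782 and Pearson's r of 0.946 on log10 values. This is a relation across peaks, which are not independent replicates, and no p-value was attached. The joint peaks were kept by IDR because the replicates ranked them consistently, so a high correlation across them is partly fixed by that choice. The joint list also held 122 peaks that overlapped a stronger listed peak, so that it covered 1615 separate regions.

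**Figure D1:**
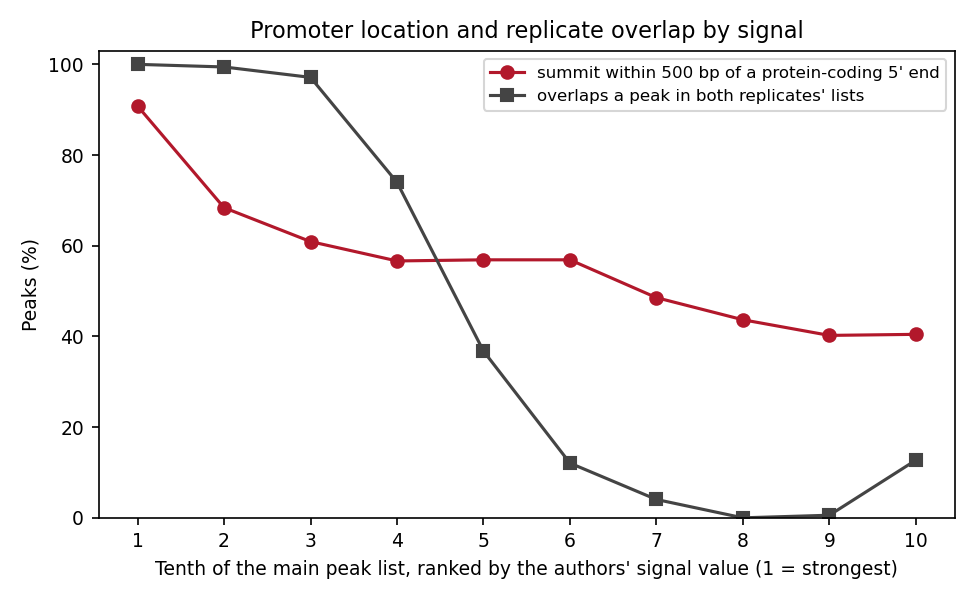
Share of the 1737 joint peaks (y axis, percent) for 10 equal parts of the list ranked by the authors' signal value (x axis, 1 is the strongest), for peaks with a summit within 500 bp of a protein-coding 5' end (circles) and peaks that overlap a peak in both replicates' own lists (squares). The promoter share fell from 90.8% in the strongest part to 40.5% in the weakest. The share in both replicates' lists fell from 100% to 0% in part 8, and was 0.575% in part 9 and 12.7% in the weakest. The weakest part holds all peaks with a signal below 60, of which 114 of 121 overlapped a stronger listed peak.

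The tagged gene itself carried a peak. At attf-3 (WBGene00018794, chromosome III, 69850 to 86384, minus strand) the joint list had a peak from 86400 to 86667 with its summit at 86525, 141 bp upstream of the annotated 5' end, and its signal of 832.02 ranked 115 of 1737. Replicate 1 had this peak with a signal of 433.79 and rank 102 of 964, and replicate 2 with 405.19. No summit lay within 500 bp of the 5' ends of attf-2, attf-4, attf-5 or attf-6, the other genes of that name. The closest summit to attf-2 was 514 bp away, and those to attf-4, attf-5 and attf-6 were 15577, 18334 and 33722 bp away. The tag was inserted at attf-3, and whether it affects the signal there was not tested.

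The next question was where in relation to genes the peaks lay. Of the 25 highest peaks, 24 had the 5' end of a protein-coding gene within 500 bp. The strongest had its summit at -141 bp from the 5' end of cmtr-1 (chromosome II, peak 15025722 to 15026215), where negative distances are upstream. It was followed by peaks at the ribosomal protein gene rps-28 (signal 4451.43, -432 bp), the mitochondrial import gene timm-23 (3367.08, -252 bp), the dihydrolipoamide dehydrogenase gene dld-1 (3088.42, -245 bp) and the RNA polymerase subunit gene rpb-12 (3047.14, -292 bp). Peaks nearest T23F6.3, mrps-7, F13G3.10, wago-4 and aps-1 came next, with signals from 2936.57 to 2163.11. The remaining peaks of the 25 lay at eif-3.E, Y50D4C.5, C26B2.7, C29E4.12, prp-8, F53H1.4, orc-5, R04F11.2, C50B6.3, F02C12.3, picd-1, farl-11, mrpl-49 and rpb-3, and at a site on chromosome IV without a near 5' end, down to a signal of 1723.47 at rpb-3. In 11 of the 25 more than 1 protein-coding 5' end lay within 500 bp, as at the pair of aps-1 and the proteasome gene rpt-2, and the peaks do not tell which gene of such a pair the protein acts on.

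Over the whole joint list, 979 of 1737 summits (56.4%, 54.02 to 58.7%) lay within 500 bp of a protein-coding 5' end, against a mean of 18.8% (SD 0.936) for 10000 random placements on the same chromosomes. The permutation test, one-sided, gave p = 0.0001, the smallest that these placements can give. Replicate 1's own list had 64.1% of 964 summits there and replicate 2's list 62.4% of 1063. Of the 979 promoter summits, 828 lay upstream of the 5' end and 151 at or downstream of it, with a median distance of -149 bp and quartiles of -254 and -50 bp. By annotation, 1177 summits (67.8%, 65.5 to 69.9%) lay outside protein-coding genes, 361 (20.8%) in introns, 91 (5.24%) in coding exons, 71 (4.09%) in 5' UTRs and 28 (1.61%) in 3' UTRs.

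A further 356 summits (20.5%, 18.7 to 22.5%) lay over 2000 bp from any protein-coding 5' end. The strongest of these, with rank 16 and a signal of 1906.08, was on chromosome IV from 12621699 to 12622065, outside protein-coding genes and at -7168 bp from the nearest 5' end. The others of the 5 strongest were in an intron of T26C5.3 (chromosome II, summit 9243037, signal 1045.85), between genes on chromosome IV (summit 8665989, 863.01), in an intron of Y69A2AR.1 (chromosome IV, summit 2670860, 828.34) and within 200 bp of a pseudogene on chromosome IV (summit 4728035, 795.25). All 5 were in both replicates' lists.

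Several lists of genes of the basic machinery of the cell were bound more often than other genes. Of 81 cytosolic ribosomal protein genes, 50 were bound, meaning that a summit lay within 500 bp of the 5' end (61.7%, 50.8 to 71.6%), against 5.84% of other genes, with an odds ratio of 25.998 and an adjusted exact p of 7.29e-39. In the replicates' own lists 53.7% ± 0.873 (SD, n = 2) of these genes were bound, and rps-28, rpl-33 (1754.77), rpl-28 (1729.08) and rpl-18 (1294.64) had the highest signals. The median summit of the bound ribosomal protein genes lay at -290 bp from the 5' end (quartiles -357.75 and -242), and a window of 250 bp left 12 of the 81 bound (14.8%, odds ratio 4.34, adjusted exact p = 0.000272), while giving each peak only to its nearest gene left 33 (40.7%, odds ratio 8.84). Of 45 genes of the respiratory chain and ATP synthase, 20 were bound (44.4%, odds ratio 12.6, adjusted exact p = 3.48e-12; 31.1% ± 3.14, SD, n = 2), led by cox-10 (1457.59), asb-2 (935.68), cox-16 (856.69) and nuo-6 (791.86), with 11 bound at 250 bp and 13 in replicate 2's own list. Of 70 mitochondrial ribosomal protein genes, 19 were bound (27.1%, odds ratio 5.84, adjusted exact p = 1.93e-07), led by mrps-7 (2545.4), mrpl-49 (1729.08), mrpl-40 (1306.34) and mrps-31 (1214.55). Stratified by distance to the next 5' end, the Mantel-Haenszel odds ratios were 13.0 (95% interval 8.08 to 21.04) for cytosolic ribosomal proteins, 6.48 (3.53 to 11.9) for the respiratory chain and 3.35 (1.95 to 5.75) for mitochondrial ribosomal proteins. All 36 lists were fixed before the data were examined and tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, against the 1212 bound of 19973 protein-coding genes (6.07%). Higher shares were found for 18 lists and lower shares for 6, and 12 did not pass.

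Genes of protein synthesis, quality control and RNA production followed. Of 39 translation factor genes, 12 were bound (30.8%, adjusted exact p = 7.19e-06), led by eif-3.E (2128.91), eif-3.B (1019.59), eif-6 (988.66) and eif-2Bgamma (944.05). Of 33 proteasome genes, 11 were bound (33.3%, adjusted exact p = 7.19e-06), led by rpt-2 (2163.11), pas-4 (1723.47), pbs-2 (988.66) and rpn-3 (349.03); replicate 1's own list had 6 (18.2%), replicate 2's 7 (21.2%), and the window of 250 bp 7. Chaperone genes were bound at 15 of 62 (24.2%, adjusted exact p = 9.57e-06), with dnj-22 (1433.56) and the chaperonin subunit gene cct-8 (1016.26) highest, and ubiquitin conjugation genes at 9 of 50 (18%, adjusted exact p = 0.00465), with ubc-20 (964.05) and cdc-48.1 (904.19) highest. Splicing and Sm protein genes were bound at 12 of 43 (27.9%, adjusted exact p = 1.73e-05), with prp-8 (1951.74), a core spliceosome component, and lsm-5 (814.08) highest. RNA polymerase subunit genes were bound at 6 of 22 (27.3%, adjusted exact p = 0.00272), with rpb-12 and rpb-3 highest. Nucleolar and ribosome assembly genes were bound at 8 of 28 (28.6%, adjusted exact p = 0.000421), with rbd-1 (2936.57) and nol-10 (1043.49) highest. The symbol pattern also took in nstp-10 (112.91), whose symbol only begins like that of the nst genes, so the 8 need not all be nucleolar. It was named after its value was seen. Nuclear pore genes were bound at 7 of 26 (26.9%, adjusted exact p = 0.00137), with npp-13 (1095.02) and npp-23 (889.48) highest. The call for RNA polymerase subunits was lost with a window of 250 bp, with 3 bound and an adjusted exact p of 0.0755 (range over the alternatives 8.94e-05 to 0.0755). With that window 9 chaperone, 7 splicing and 5 nucleolar genes were bound, and replicate 1's own list also had 5 nucleolar genes.

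Lists of replication, cell cycle, chromatin regulator, P granule and Argonaute genes were also bound more often, while histone, spermatogenesis and major sperm protein genes did not pass. DNA replication genes were bound at 11 of 33 (33.3%, adjusted exact p = 7.19e-06), with the origin recognition gene orc-5 (1842.94) and rfc-4 (712.32) highest, and at 7 in replicate 1's own list. Cell cycle, centrosome and kinetochore genes were bound at 17 of 72 (23.6%, adjusted exact p = 4.69e-06), with the cyclin B gene cyb-1 (1842.94), cdc-48.1 (904.19), which is also counted among the ubiquitin genes, and the Aurora kinase gene air-1 (857.78) highest; orc-5 and cyb-1 share a peak. Chromatin regulators were bound at 23 of 122 (18.9%, adjusted exact p = 4.69e-06), with dpl-1 (769.09), set-21 (457.26), lin-54 (409.63) and lin-9 (393.66) highest. The set-21 peak is shared with the ribosomal protein gene rpl-7A and the lin-54 peak with rpl-12. Of the chromatin regulators, 15 were bound at 250 bp. The symbol pattern also took in metl-17 (353.31), metl-1 (180.12) and metl-6 (119.55), whose names are those of methyltransferase-like genes, and mesp-1 (107.94), and all of these were named after their values were seen. P granule and germline RNA regulators were bound at 10 of 50 (20%, adjusted exact p = 0.00137), with mog-4 (816.15), pos-1 (265.25) and mex-1 (227.55) highest. Argonaute and small RNA genes were bound at 13 of 79 (16.5%, adjusted exact p = 0.00159), with the germline Argonaute gene wago-4 (2185.9) and tofu-5 (791.86) highest.

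Meiosis and DNA repair genes were bound at 9 of 61 (14.8%, adjusted exact p = 0.0163), with the checkpoint kinase gene chk-1 (1337.31) and syp-2 (856.69), of the synaptonemal complex, highest. Eggshell and oocyte genes were bound at 9 of 36 (25%, adjusted exact p = 0.000486), with perm-5 (386.59) and cpg-1 (208.62) highest. The meiosis call was lost in replicate 1's own list (odds ratio 2.61, adjusted exact p = 0.0536), in the stronger 868 peaks (2.68, 0.0504) and at an IDR of at most 0.001 (2.49, 0.0645), over a range of p from 0.00118 to 0.0645, and its odds ratio of 2.69 over the joint list was 1.55 (95% interval 0.755 to 3.17) when stratified by distance to the next 5' end. The eggshell call was lost in replicate 2's own list, with 4 bound and an odds ratio of 2.72 against 5.19 (adjusted exact p = 0.104), and in the stronger 868 peaks, with 4 bound and 3.07 (0.0774), over a range of p from 0.000141 to 0.104. Of its 9 bound genes, 2 had a peak in both replicates' lists. With each peak given only to its nearest gene, the Argonaute list had 9 bound and an adjusted exact p of 0.252 (range 0.000205 to 0.252). With a window of 250 bp, the P granule list had 5 bound and an adjusted exact p of 0.0668 (range 8.36e-05 to 0.0668).

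Several lists of large gene families, among them chemoreceptor and immunity genes, were bound less often than other genes. Of 1365 chemoreceptor genes, 8 were bound (0.586%, 0.297 to 1.15%, odds ratio 0.0852, adjusted exact p = 2.10e-26), led by srd-4 (599.38), srh-16 (276.26) and sri-5 (260.53). The symbol pattern also took in srp-7 (141.31), whose name is that of a serpin gene and which was named after its value was seen. F-box, MATH and BTB genes were bound at 4 of 438 (0.913%, adjusted exact p = 5.25e-07), with bath-41 (909.77) highest; the cullin gene cul-4 (187.07) was also counted, and was named after its value was seen. Innate immunity and lectin genes were bound at 3 of 394 (0.761%, adjusted exact p = 5.51e-07), with clec-126 (149.34) highest. Detoxification genes were bound at 1 of 208 (0.481%, adjusted exact p = 0.00014), at gst-27 (141.85), and nuclear hormone receptor genes at 3 of 269 (1.12%, adjusted exact p = 0.000209), with nhr-47 (248.75) highest. Neuropeptide and insulin genes were bound at 1 of 140 (0.714%, adjusted exact p = 0.00561), at flp-23 (86.56), and that call was lost when each peak was given to its nearest gene (adjusted exact p = 0.0542, range 0.00052 to 0.0542). With the nearest gene, which counts peaks at any distance, 20 chemoreceptor, 11 F-box, 10 nuclear hormone receptor, 7 immunity, 4 detoxification and 4 neuropeptide genes were bound. In the lists of replicate 1 and replicate 2, 5 and 6 chemoreceptor, 1 and 2 nuclear hormone receptor, 1 and 0 immunity, and 0 and 1 detoxification genes were bound, and no neuropeptide gene was.

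The lists that mark differentiated tissues did not pass the test. None of 46 muscle genes, 43 intestine genes, 31 major sperm protein genes or 6 vitellogenin genes was bound, which allows shares of up to 6.52%, 6.98%, 9.68% and 50%, so that a share below 6.07% was not detectable with lists of this size. Collagens were bound at 6 of 176 (3.41%, adjusted exact p = 0.198), with col-85 (242.36), col-72 (185.07), col-71 (179.9) and col-38 (155.23) highest. Histone genes were bound at 6 of 72 (8.33%, adjusted exact p = 0.477), with his-37 (197.85), and with his-67 and his-68 at a shared peak (119.98). The other lists without a call were neuronal and synaptic genes (4 of 97, adjusted exact p = 0.542), homeobox factors (2 of 78, 0.376), spermatogenesis (1 of 62, 0.228), aminoacyl-tRNA synthetases (3 of 32, 0.477), the vacuolar ATPase (3 of 20, 0.157) and the attf family (1 of 5, 0.312). Their bound members, named after their values were seen, were unc-101, mec-6, ric-8 and unc-116, ceh-38 and ceh-39, try-5 (849.95), ears-2, nars-1 and kars-1, vha-18, vha-8 and vha-13, and attf-3. Collagens were called lower with a window of 250 bp (1 bound, adjusted exact p = 0.0258, range to 0.872) and neuronal genes in replicate 2's own list (0 bound, 0.0343, range to 0.858), and the vacuolar ATPase higher in the list from pooled reads (4 bound, 0.0418, range to 1). Nearby genes of the same list or of different lists can share a peak and are then not independent. Pairs from different lists included rpl-7A with set-21, rpl-12 with lin-54, nuo-6 with tofu-5 and cox-16 with syp-2. In such pairs 1 peak counted for more than 1 list. All calls of the 36 lists were the same by a rotation of the bound genes along the gene order.

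**Figure D2:**
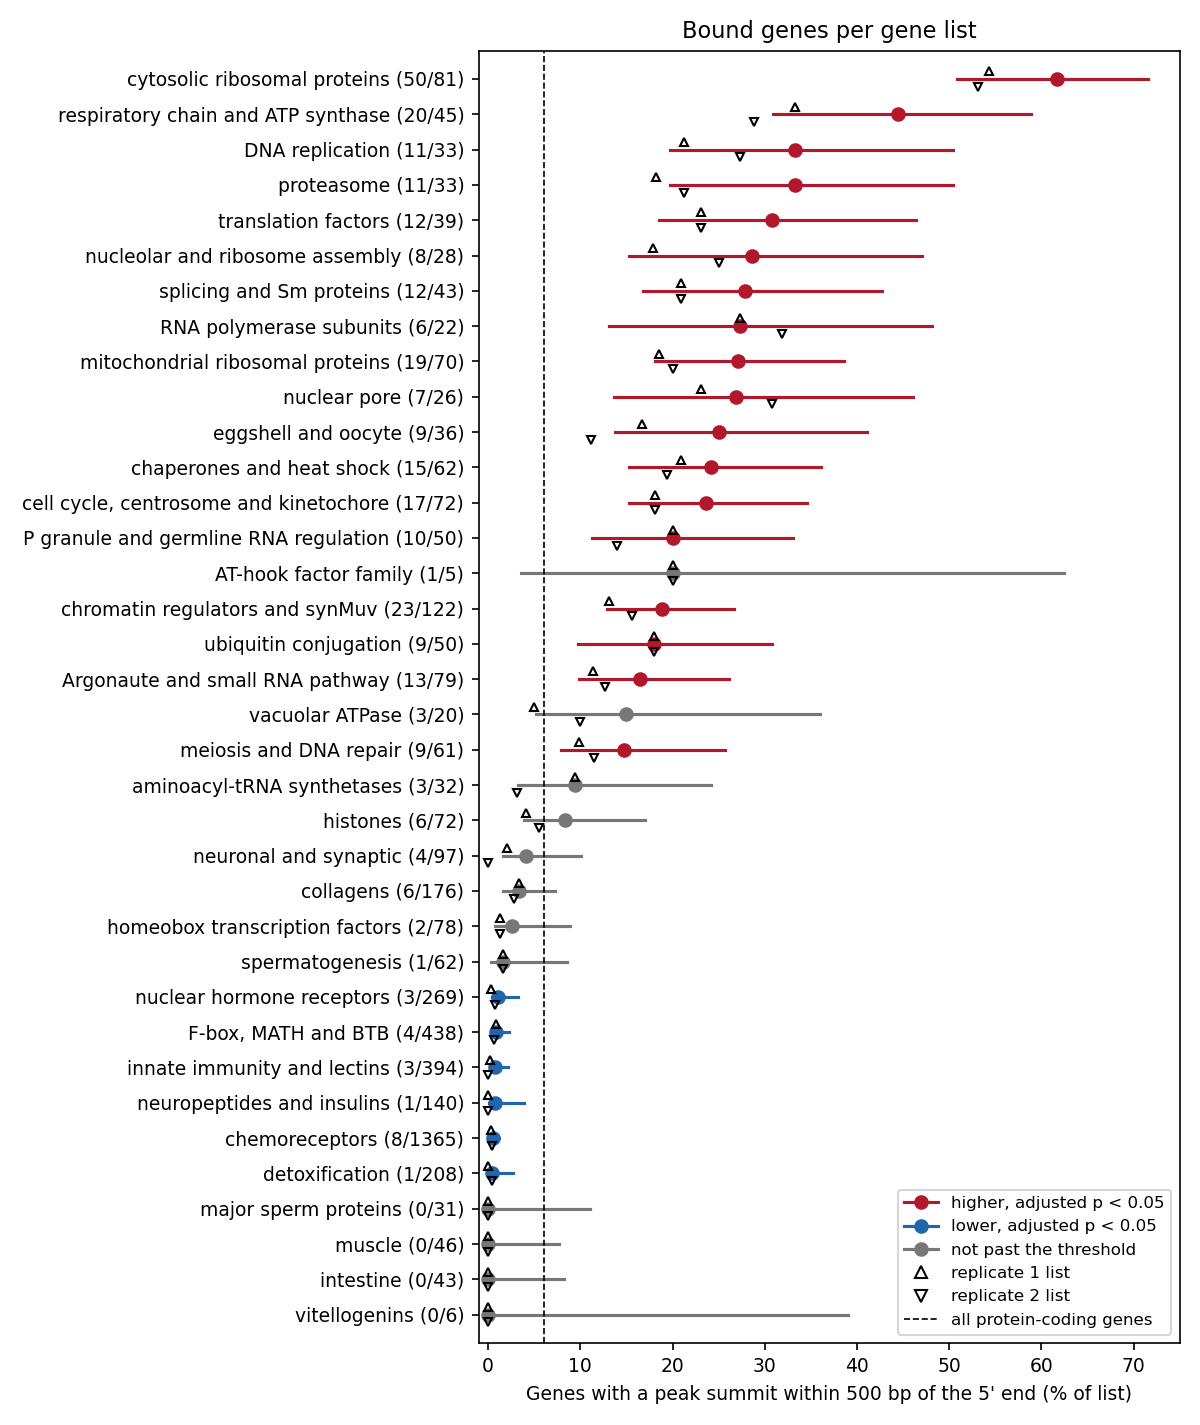
Percent of the genes of each of the 36 lists with a summit within 500 bp of the 5' end (x axis), with bound and listed genes in parentheses. Circles are the joint list with 95% Wilson intervals, triangles the lists of replicate 1 and replicate 2, and the dashed line is the share of all protein-coding genes, 6.07%; the cytosolic ribosomal proteins are highest with this window, at 61.7%, and with a window of 250 bp they are at 14.8%, below DNA replication at 27.3%.

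Genes for small structural RNAs had summits more often than random placements gave. Of 612 tRNA genes, 156 (25.5%) had a summit within the gene or 200 bp around it, against a mean of 4.24 (SD 2.12) for random placements. Replicate 1's own list had 64 (10.5%), replicate 2's 83 (13.6%) and the stronger 868 peaks 66 (10.8%). The highest signals at tRNA genes were at WBGene00014332 (chromosome I, 11579706 to 11579778, signal 416.04), WBGene00022908 (chromosome X, 353255 to 353336, 299.9) and WBGene00014567 (chromosome V, 19126044 to 19126116, 274.59). Of 129 snRNA genes, 27 (20.9%, random mean 1.23, SD 1.11) had a summit, led by the spliced leader gene sls-2.1 (360.97), T11F9.15 (326.36) and mir-1831 with the overlapping sup-39 (315.89), and 20 (15.5%) and 17 (13.2%) had one in the lists of replicate 1 and replicate 2. Of 346 snoRNA genes, 66 (19.1%, random mean 3.49, SD 1.89) had a summit, led by Y53F4B.47 at the cmtr-1 peak, F59C6.15 (461.7) and D1046.6 (455.77), and 47 (13.6%) and 52 (15.03%) had one in the replicates' lists. Other annotated ncRNA genes had a summit at 334 of 7764 (4.30%, random mean 66.9, SD 9.56), and at 170 and 195 in the replicates' lists.

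The genes of piRNAs, short germline RNAs, had fewer summits than random placements gave: 13 of 15363 (0.0846%) against a mean of 124 (SD 17.3), the highest at 21ur-13751 (313.68), 21ur-12279 (289.74) and 21ur-11151 (266.94). Summits placed at the same distances from other promoters gave a mean of 73.4 (SD 12.3). Only 3 of the 13 genes had their summit outside the 500 bp around any protein-coding 5' end. The summit at 21ur-12279 lay at the 5' end of atp-1, and that at 21ur-13751 at -417 bp from vig-1. The lists of replicate 1 and replicate 2 had 9 and 8 piRNA genes with a summit, and no piRNA gene widened by 50 bp had one in the joint list. Each of these 5 classes had an adjusted p of 0.00032 by the two-sided permutation test with 10000 placements, from the smallest p that they can give, adjusted over 8 classes. The classes of miRNA (6 of 261, adjusted p = 0.0893), long ncRNA (11 of 294, 0.376) and rRNA (0 of 20, adjusted p = 1) did not pass by this permutation test. Within 200 bp of an rRNA gene, 2 peaks passed the IDR threshold in the ranked list but are absent from the joint list. The rRNA count therefore does not show that signal was absent there. The miRNA class passed in the list from pooled reads (adjusted permutation p = 0.0133) and in the lists of replicate 1 (0.0424) and replicate 2 (0.0235), with genes widened by 50 bp (0.0411) and against like-placed summits (0.0448), within a range of 0.0133 to 0.274 over the alternatives. For tRNA genes, 127 of the 156 had their summit outside the 500 bp around any protein-coding 5' end, and 40 had a peak that was in both replicates' lists. Reads from near-identical tRNA and snRNA copies can be split or lost in alignment, and how they were handled is not given in the sources used here.

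**Figure D3:**
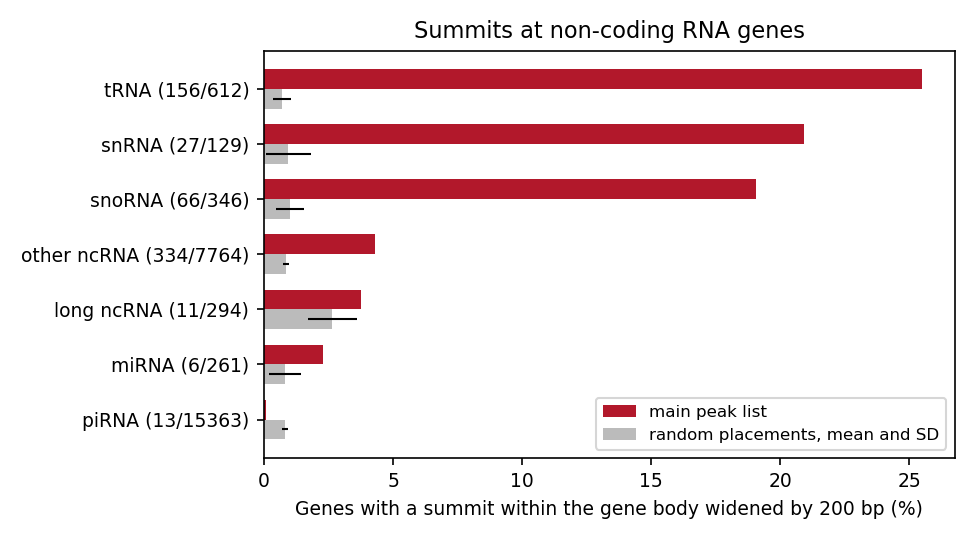
Percent of the genes of each non-coding RNA class with a summit in the gene body widened by 200 bp (x axis), for the joint list (red) and for random placements (grey, mean and SD). The tRNA, snRNA and snoRNA genes are at 25.5%, 20.9% and 19.1%, and piRNA genes are at 0.0846%. In replicate 1's own list tRNA genes are lowest of the first 3, at 10.5%. The 20 rRNA genes, with no summit in the joint list, are not drawn.

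Chromosome X held fewer peaks than the autosomes. It carried 155 peaks, or 8.75 per Mb, against 19.2 per Mb on the autosomes, a ratio of 0.456 (permutation test, two-sided, p = 0.0002, the smallest possible). The lists of replicate 1 and replicate 2 gave ratios of 0.331 and 0.431. In proportion to gene number, 238 peaks would lie on X (two-sided permutation p = 0.0002). Of 2731 protein-coding genes on X, 54 (1.98%) were bound, against shares from 4.27% on chromosome V to 8.93% on chromosome I. Of the 1582 autosomal peaks, 695 (43.9%) lay in the central of 3 equal parts of their chromosome, against a random mean of 33.3% (p = 0.0002) and one of 38.6% for placements drawn from gene 5' ends (p = 0.0002), both by two-sided permutation tests.

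The DNA at the summits was less rich in A and T than like-placed DNA. The summits with 50 bp on either side held 53.5% ± 8.76 (SD over 1737 peaks) A or T, against 64.97% in windows placed at the same distance and side of the 5' ends of unbound genes, a difference of -11.5 percentage points (two-sided permutation test, p = 0.0002, the smallest possible). In replicate 1's list the difference was -11.3 and in replicate 2's list -11.5 points. With 100 bp on either side of the summit it was -7.33 points, and against windows at 1000 bp from the same summits -8.85 points. Among tRNA genes the summits held 50.01% A or T, and at promoters 54.3%.

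Of 2080 6-mers, 753 were more frequent and 594 less frequent at summits than in control windows (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). The leading one, ACGCGC with its reverse complement GCGCGT, was in 281 windows (16.2%) against 1.42% of control windows, an 11.4-fold difference with an adjusted exact p of 1.17e-126. The palindrome GCGCGC was in 11.9% against 0.633%, an 18.6-fold difference. A separate family led by ACTCCG was in 210 windows (12.1%) against 1.76% (6.85-fold, adjusted exact p = 1.67e-71). Control windows were not matched for base composition, and 6-mers that overlap are not independent.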

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

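The test against strongly transcribed genes and the comparison of weaker peaks for the motifs were chosen only after the result was seen; the test of crowding over all lists was added after the lists' shares were seen, with its bounds set before its own result. The ranked list of the joint peaks held 1820 peaks past the IDR threshold, and 83 of them (4.56%) are absent from the thresholded list, a signal outside the peaks compared above. Of the 83, only 2 (2.41%) had a summit within 500 bp of a protein-coding 5' end, they fell into 44 regions more than 10000 bp apart, and their median signal was 215. The strongest had as their nearest genes Y7A5A.7 on chromosome X (summit 15811110, signal 1705.43), clec-9 on chromosome V (summit 16708988, 1487.62) and elk-2 on chromosome X (summit 110505, 1442.84). Of the 83, 2 lay within 200 bp of an rRNA gene, and none lay so near a tRNA, snRNA or snoRNA gene. Why the 83 peaks are absent is not given in the sources used here.

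In 18 lists, most of them of basic cell functions, genes were bound more often than others, as at 50 of 81 cytosolic ribosomal protein genes. Stratified by distance to the next 5' end, the Mantel-Haenszel odds ratio of the ribosomal protein genes was 13.0 (95% interval 8.08 to 21.04) against 25.998 without strata, so crowding of 5' ends went with part of the excess and not with all of it. The lower limit stayed above 1 for 17 of the 18 lists with higher shares, and meiosis and DNA repair was the exception (odds ratio 1.55, 0.755 to 3.17). Signal at any strongly transcribed gene stays open: the muscle, collagen, vitellogenin, major sperm protein and intestine lists were bound at 6 of 302 genes together (1.99%, exact Clopper-Pearson interval 0.733 to 4.27%, against 6.07% of all genes), but their counts had been seen and transcription was not measured here. Signal at promoters that are open in most cells stays open too, since its test needs worms that express GFP alone and was not analysed here; the design gives no group for a biological explanation, and none was tested.

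Summits at tRNA genes could come from neighbouring promoters of protein-coding genes, but 156 tRNA genes had a summit, while summits placed at the same distances from other promoters reached at most 13 (mean 3.36). The sequence motifs of the strongest promoter peaks, described among the other observations, were in 5.98% of the 117 tRNA peaks outside promoters (exact interval 2.44 to 11.9%), against 27.1% of promoter peaks (Fisher's exact test, p = 4.83e-08). The bound written beforehand for excluding the motifs, a share below 5%, was not met. Among peaks beyond rank 300 the shares were 6.03% and 9.96% (Fisher's exact test, p = 0.230), so the difference may come from the lower signal of tRNA peaks rather than their place. Whether the motifs bring the protein to tRNA genes stays open for the 7 peaks that carry them. Signal at any strongly transcribed gene stays open for the tRNA, snRNA and snoRNA genes too. Transcription was not measured, and worms that express GFP alone were not analysed here. No biological explanation was tested.

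Low AT content reached into the weaker peaks. Coding exons do not account for it: weaker summits outside coding exons lay -12.4 percentage points from controls outside coding exons (54.04% against 66.45%, standard error 0.342). Recovery of GC-rich fragments may contribute, since signal rose with GC percent across ranked peaks outside the joint list, with Spearman's rho of 0.151 in replicate 2 and 0.188 in replicate 1, over 36053 and 41725 peaks, which are not independent. Binding to GC-rich sites gives the same relation, and no biological explanation was tested.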

How the results depend on the processing

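Alternatives with an IDR of at most 0.001, any transcript's 5' end, like-placed summits and joined peaks were chosen after seeing the data. Over all alternatives, 93 of 100 values were counted as the same and none reversed. For tests this meant the same direction and side of the threshold. Counts of calls and correlations were allowed a fixed tolerance, which is not a spread, so a count could lose calls and still be the same. The count of lists called higher, 18 over the joint list, was 16 in the stronger 868 peaks and with a window of 250 bp, and 19 in the list from pooled reads. The other 7 of the 100 values concern the replicates. Spearman's rho of replicate signals, 0.782 over the joint list, was 0.864 in the stronger 868 peaks, 0.851 at an IDR of at most 0.001, and 0.880 to 0.883 in the peaks of each replicate's own list. In the list from pooled reads it was lower, at 0.732 (Pearson's r on log10 values 0.879), which fell within the tolerance and was counted as the same. The joint peaks and their stricter cuts were kept for consistent ranking in both replicates, which bears on their correlation. The share of peaks in both replicates' lists, 43.7%, was 37.4% with a reciprocal overlap of 50%, 81.6% in the stronger 868 peaks and 76.1% at an IDR of at most 0.001. The reciprocal overlap changes the overlap rule and the other settings change which peaks are kept, and beyond this the cause was not tested. Calls of single lists and non-coding classes were the same in 477 of 494 cases, were lost in 9 and were gained in 8. Of 110 genes named by the rule, at least 100 kept a summit under each alternative list, the fewest in replicate 2's own list. Depth is unknown, so what it limits could not be assessed.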

Other observations

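The motif models, their tests on even-ranked peaks and the signal bound of 60 were chosen only after the result was seen. Windows around a pair of sequences frequent in the strongest peaks gave longer motifs. Motif 1, built on ACTCCG in odd-ranked peaks, had the consensus AACGACACTCCGNNATNNCG, and motif 2, built on TAAACA, had CGNTAAACAACNCGC, where N is a base below 60%. Of the 87 even-ranked peaks in the strongest of 10 equal parts of the joint list, 87.4% carried motif 1 and 73.6% motif 2, and of the 86 in the weakest part 3.49% and 3.49%. All 25 of the highest peaks, odd-ranked ones used for the models included, carried at least 1 of them and 17 both, as at timm-23, dld-1, rpb-12 and wago-4, while cmtr-1 and rps-28 carried motif 1 only. Of 218 peaks with both motifs, 89 had the motif centres 23 bp apart, and in 190 the matches shared no base.

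The hypothesis that the motifs hold in peaks they were not built from was tested on the 868 even-ranked peaks. Motif 1 was in 17.6% of them against 1.17% of control windows (Fisher's exact test, p = 9.20e-80), and motif 2 in 16.7% against 0.691% (p = 1.61e-86). The seeds were chosen by looking at strong peaks of all ranks, even ones included, so these peaks are not an independent sample. The motif score threshold was set so that 1% of windows lay above it, so a control share near 1% may follow from that setting. Base composition of the control windows was not matched here either. In the genome, the exact core of motif 1 occurred 98 times and 58 copies (59.2%, 49.3 to 68.4%) had a joint summit within 100 bp, with 41 of 52 copies near 5' ends (78.8%) and 17 of 46 elsewhere (36.96%). Against the 71287 peaks of the ranked list before the threshold, the counts were 42 of 52 (80.8%) and 30 of 46 (65.2%). The core of motif 2 occurred 122 times, with 57 bound (46.7%, 38.1 to 55.5%), 39 of 52 near 5' ends and 18 of 70 elsewhere, and with the ranked list 43 of 52 (82.7%) and 38 of 70 (54.3%). The difference between places was not tested. The motifs came from 91 and 94 sites in odd-ranked joint peaks, and these sites were not taken out of the counts. The shares with a summit can therefore be raised by that choice, and are not an independent measure of how often a copy is bound. Among the 49 peaks at cytosolic ribosomal protein promoters 9 carried either motif (18.4%), against 27.5% at other promoters (Fisher's exact test, adjusted p = 0.188). Motif 2, with or without motif 1, was in 8.16% of them against 22.5% (Fisher's exact test, adjusted p = 0.0269), and motif 1, with or without motif 2, in 14.3% against 23.3% (Fisher's exact test, adjusted p = 0.185).

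A further hypothesis was that ribosomal protein genes without a peak lie downstream of a close gene on the same strand, as in worm operons. Such a neighbour within 1000 bp was present at 32.3% of the 31 unbound genes (10 genes) and at 32.0% of the 50 bound genes (16 genes). Fisher's exact test, two-sided, gave p = 1. The result written beforehand as going against the hypothesis, an equal or lower share at unbound genes, was not met. With so few genes the test does not decide the question. Among the weakest peaks, 121 had a signal below 60, and 114 of these (94.2%) overlapped a stronger listed peak, against 8 of the peaks above that bound.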
